A study of Mus musculus with 12 samples.

How the data were processed

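The samples were 12 libraries of total RNA from C57BL/6 mouse embryos at the 2-cell stage, 6 per genotype. Per the labels' protocols, embryos of both genotypes were sampled at the same time, washed, lysed in individual tubes and turned into libraries with a stranded kit for low input that depletes ribosomal RNA. Sequencing was paired-end on a NextSeq 500, per the series' design text. The submitters' processing notes name the mm10 genome build, Trimmomatic 0.32 and edgeR, without saying what each was used for. The aligner, the repeat annotation and the counting program are not given in the sources used here.

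The deposited values are estimated counts of reads per repeat name, with its class and family. The names given to the deposited tables carry words for unique reads and for fractions, and how these were combined is not given in the sources used here. All deposited counts were whole numbers (0 files held a value that was not whole), so rounding of estimated counts changed nothing and no test on unrounded counts was run. Whether the rounding was done by the authors, and whether strand was used in counting, is not given in the sources used here. Repeats of near-identical sequence can share reads, so the separate levels of related names are uncertain. The counts of repeats can also take in reads from genes that carry a repeat in their introns or untranslated regions.

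The plan, written before the data were examined, allowed for genes and for repeats. The files held repeat rows only, so the tests planned for repeats were run and those for genes, the level of Kdm4a and the lists of genes were not analysed here. The rules written for genes (test, alternatives, choice of named items) were applied to repeats. The 5 lists of repeats fixed beforehand were MERVL (7 names), MT of the ERVL-MaLR family (10), IAP (25), LINE-1 (25) and SINE (6). Groups and replicate numbers were taken from the sample titles. The number in a file name runs opposite to that in the title, and the titles were used.

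Repeats were tested with edgeR 4.0.16 in R 4.3.3. Rows were kept by filterByExpr with the group, library sizes were taken from all rows, and TMM factors corrected for composition. The quasi-likelihood F test compared KO with WT with genotype as the only term, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Standard errors of log2 fold changes were taken from the F statistic. Normalised CPM values use the library sizes times the TMM factors. Lists were tested with camera on voom values (limma 3.58.1) with a preset correlation of 0.01 and with an estimated correlation, and with fry. Camera p-values were adjusted over the 5 fixed lists, and separately over the 38 families of the annotation with at least 4 tested rows.

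Shares of counts and ratios within a library were compared by exact permutation tests over all 924 regroupings of the libraries (two-sided, scipy 1.17.1), adjusted over 20 comparisons. Correlations used all pairings of 6 libraries. The repeats named in the text were chosen by a rule. It took up to 10 higher and 10 lower repeats with the largest log2 fold changes among calls with a mean of at least 10 normalised CPM over all libraries, leaving out names that are only model numbers. It also took from each list up to 4 called members with the smallest p, or, where none was called, the 2 members with the smallest p. The rule gave 3 higher repeats, since no more passed. Repeats named outside the rule are said to have been chosen after their values were seen.

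The depth of 7952526 to 18902360 counts per library was spread over few abundant names and many rare ones, and the tested rows held over 99% of the counts of each library. On simulated counts for the 3312 tested repeats, drawn from the real means, library sizes and dispersions with 200 repeats changed, the edgeR test recovered 27.9% of 68 repeats with a log2 change of 0.6, 49.3% of 69 with a change of 1 and 76.2% of 63 with a change of 2. Among those with a mean of at least 10 CPM, the recovered shares were 55.9%, 93.8% and 100%. Of 107 simulated calls, 6 were of unchanged repeats, and a simulation with no change gave 0 calls. Rare repeats could therefore change by a log2 value of 1 without being called. Reads without molecular identifiers are not independent molecules.

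Replicates were compared in pairs within each group, 30 pairs in all. The chi-square per degree of freedom lay between 29.6 and 175.6, so no pair agreed within sampling noise. On principal components, WT replicate 2 lay apart on the first component (21.7% of the variance) and KO replicate 5, the shallowest library, on the second (12.2%). All libraries were kept.

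The other settings chosen beforehand were total-count, RLE and upper quartile scaling, DESeq2 1.42.0, limma-voom with quality weights, robust edgeR, other filters, a replicate block, library size as a covariate, a test against a fold of 1.5, removal of the 20 most abundant rows and removal of each library. Those chosen after seeing the data were removal of WT replicate 2 and KO replicate 5 together, TMM factors from transposon rows only, tests of transposon rows only, totals without the ERVL and ERVL-MaLR families, and shares without structural RNA or LTR rows.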

Results

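Total RNA was measured in mouse embryos of the C57BL/6 strain at the 2-cell stage, 1.5 days after fertilization. The embryos came from wild-type or Kdm4a knockout oocytes, and both kinds of oocyte were fertilized with Kdm4a knockout sperm. Kdm4a encodes a histone demethylase that removes methyl groups from lysines of histone H3. The group called WT here therefore carried a maternal Kdm4a allele and no working paternal one, and the group called KO carried neither. Each group had 6 libraries. The contrast was of the maternal allele together with the product stored in the oocyte. Any other difference between the females or oocytes of the 2 groups cannot be told apart from it. The labels place embryos in individual tubes but do not say how many embryos each library holds or how many females gave the oocytes. The p-values below, other than those of camera, measure the spread between these libraries. Camera compares listed repeats with the others, and its preset correlation of 0.01 treats repeats as nearly independent.

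The values were read counts per repeat name, that is, per family of transposable element, simple repeat or repeated structural RNA. No gene was among them, so the level of Kdm4a itself could not serve as a check of the genotype labels. Each library listed 18538 repeat names, of which 17171 were simple repeats. Total counts ran from 7952526 in KO replicate 5 to 18902360 in WT replicate 4, and their means did not differ between the groups (n = 6 each, exact permutation test, two-sided, p = 0.487). After removal of rarely counted names, 3312 repeats were tested, 2085 of them simple repeats.

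The first comparison asked how the makeup of the repeat RNA differed between the genotypes. Retrotransposons with long terminal repeats, the LTR class, made up 55.9% ± 2.05 of the counts in WT and 47.7% ± 2.88 in KO (SD, n = 6 each). All 6 KO libraries lay below all 6 WT libraries. Short interspersed elements, the SINE class, took the opposite course, with 13.9% ± 0.958 of the counts in WT and 18.8% ± 2.48 in KO, and again the groups did not overlap. DNA transposons rose from 1.25% ± 0.0806 to 1.58% ± 0.123 and simple repeats from 6.27% ± 0.377 to 7.77% ± 0.654. Each of these 4 differences had an exact permutation p of 0.0021645, the smallest that 6 libraries against 6 can give, and an adjusted p of 0.00722 over the family of 20 comparisons.

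The LINE class, the long interspersed elements, made up 10.9% ± 0.902 of the counts in WT and 12.1% ± 0.727 in KO (SD, n = 6), which did not pass the correction (exact permutation p = 0.0368, adjusted p = 0.0613). Ribosomal RNA repeats, a measure of how well ribosomal RNA had been depleted, stood at 5.74% ± 0.488 in WT and 5.55% ± 0.775 in KO (n = 6, exact permutation p = 0.626). Shares of one total are not independent, and a fall of the LTR class alone raises every other share. Among counts outside the LTR class, the SINE share was still higher, at 31.5% ± 1.12 in WT and 35.8% ± 3.11 in KO (n = 6, exact permutation p = 0.00649, adjusted p = 0.0162). The LINE share of the same counts was 24.8% ± 1.45 in WT and 23.3% ± 1.88 in KO (n = 6, exact permutation p = 0.154).

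**Figure D1:**
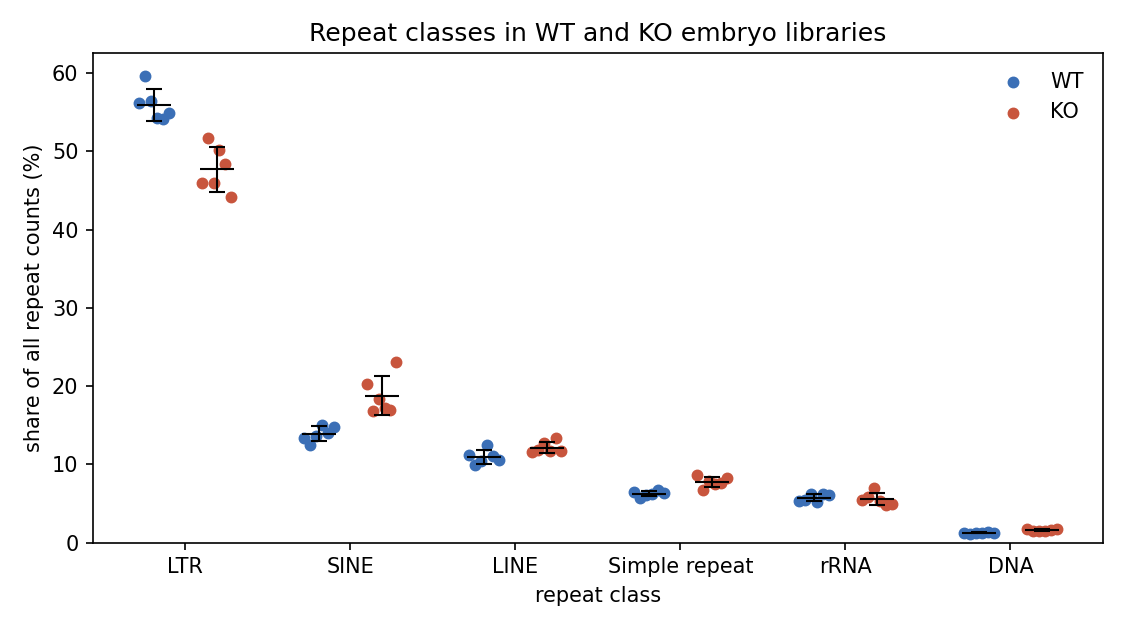
Share of all repeat counts (%) taken by 6 repeat classes, with 1 point per library, WT in blue and KO in red; black lines are the mean ± SD of 6 libraries. The LTR share lies between 54.1% and 59.6% in WT and between 44.2% and 51.7% in KO, and the SINE share between 12.4% and 15.0% in WT and between 16.8% and 23.1% in KO.

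The second comparison tested each repeat. The repeats that changed were mostly lower in KO, and most of them were LTR retrotransposons. Of the 3312 repeats, 47 passed an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 5 higher and 42 lower in KO. The lower ones comprised 26 LTR elements, 8 simple repeats, 4 LINE elements, 3 DNA transposons and 1 repeat of unknown class. In 34 of the 42, every KO library lay below every WT library. The 42 were called on these same libraries, so this separation is no separate support. No SINE was among the calls of edgeR. At an unadjusted p under 0.05, 6 SINEs were higher and 2 lower, DESeq2 called 1 lower, and limma-voom with quality weights called none, while edgeR under total-count scaling called 29 higher and 0 lower.

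These fold changes are relative to the typical repeat, whose median log2 fold change was 0.01. Scaling by total counts moved that median to 0.32 and turned the split of calls to 357 higher and 33 lower, so the excess of lower calls depended on the scaling. Changes are given relative to the typical repeat from here on. The count of calls also moved with single libraries: it was 29, 22 and 19 without WT replicate 1, 3 or 6, and 28, 93, 30, 31 and 19 without KO replicate 1, 2, 3, 5 or 6.

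**Figure D2:**
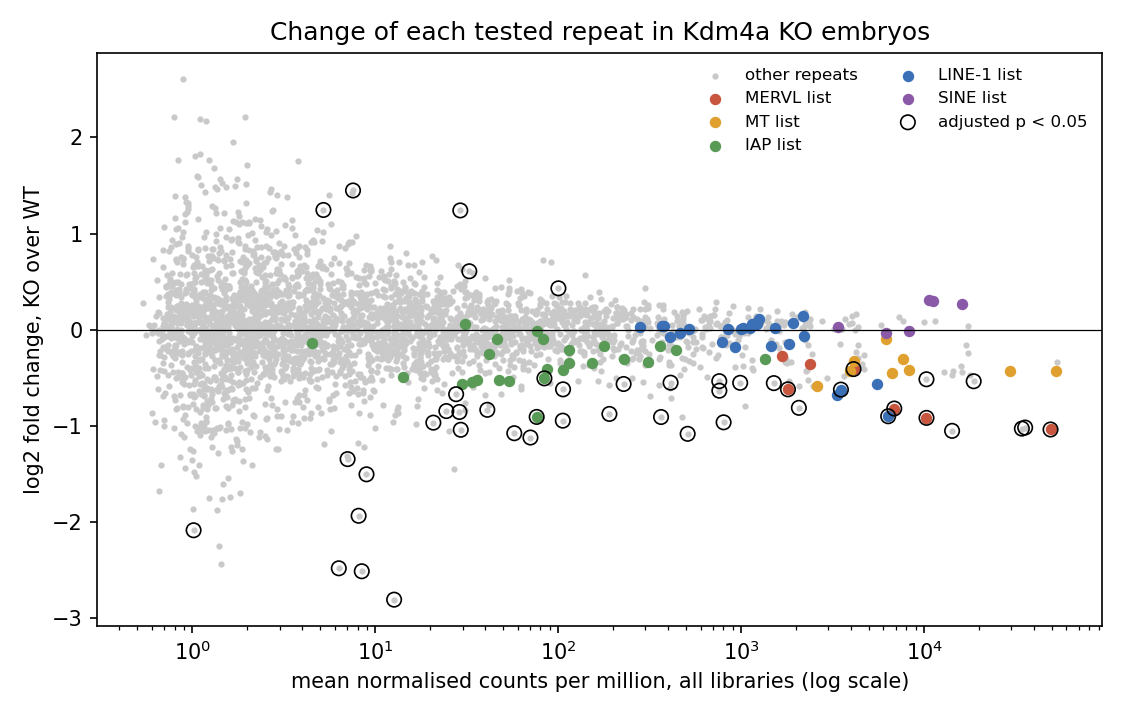
Log2 fold change of KO over WT (vertical axis) against the mean normalised CPM over all libraries (horizontal axis, log scale) for each of the 3312 tested repeats; colours mark the 5 lists of repeats fixed beforehand and black rings the 47 repeats with an adjusted p under 0.05. The MERVL list (red) lies below 0 for all 7 members, and MERVL-int is the member farthest to the right.

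MERVL, the endogenous retrovirus whose transcripts mark the 2-cell embryo, was lower in KO. Its internal part, MERVL-int, fell from 66062 ± 14862 normalised CPM (read counts scaled to a common library size) in WT to 32176 ± 8631 in KO (SD, n = 6), a log2 fold change of -1.04 with a standard error of 0.19 (edgeR adjusted p = 0.0159). Every KO library lay below every WT library. A share of all counts amounts to scaling by total counts. By that measure, MERVL-int made up 5.86% ± 0.835 in WT and 3.52% ± 0.703 in KO (n = 6, exact permutation p = 0.0021645, adjusted p = 0.00722). The long terminal repeat of MERVL, MT2_Mm, fell by 0.92 on the log2 scale (standard error 0.18, edgeR adjusted p = 0.0229), from 13478 to 7138 normalised CPM.

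Among the 7 members of the MERVL list, 5 fell and 2 did not pass the test over all repeats; adjusted over the list alone, all 7 were lower. The related terminal repeats MT2C_Mm and MT2B had log2 fold changes of -0.82 and -0.41 (edgeR adjusted p = 0.0212 and 0.0251). MT2B2, chosen after its values were seen because it was the remaining call, had a log2 fold change of -0.62 (edgeR adjusted p = 0.0314). The list as a whole was lower than the other repeats (camera adjusted p = 2.13e-11 over 5 lists), also when the correlation between members was estimated (adjusted p = 0.0300). The rotation test fry of limma gave an adjusted p of 0.00106 for MERVL, 0.0187 for each of the MT and IAP lists (all lower), 0.382 for LINE-1 and 0.348 for SINE. The edgeR calls of MT2_Mm and MT2C_Mm were lost without WT replicate 3 (adjusted p = 0.0579 and 0.0571), WT replicate 6 (0.0576 and 0.0526), KO replicate 6 (0.0687 and 0.0660) or both WT replicate 2 and KO replicate 5 (0.0609 and 0.0665), and with no filter (0.0630 and 0.0585). That of MT2B was lost under total-count scaling (log2 fold change -0.10) and without 6 single libraries (WT replicates 3 and 6, KO replicates 1, 3, 5 and 6), with edgeR adjusted p up to 0.0717.

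Close relatives of MERVL showed the same pattern, namely MERVL_2A-int, ERVL-B4-int and ERVL-int, with log2 fold changes of -1.02, -1.03 and -1.05 (each with an edgeR adjusted p of 0.0159). Their counts kept nearly the same ratio to MERVL-int in every library. For ERVL-B4-int this ratio was 0.695 ± 0.00798 in WT and 0.702 ± 0.00969 in KO (SD, n = 6). Whether reads were shared among these names is not given in the sources used here, so the 4 names are treated as 1 signal and their separate levels are uncertain. The ERVL family, to which these names belong, was not lower as a whole. Of its 105 tested repeats, 58 had a positive and 47 a negative log2 fold change (median 0.05, camera adjusted p = 0.997).

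**Figure D3:**
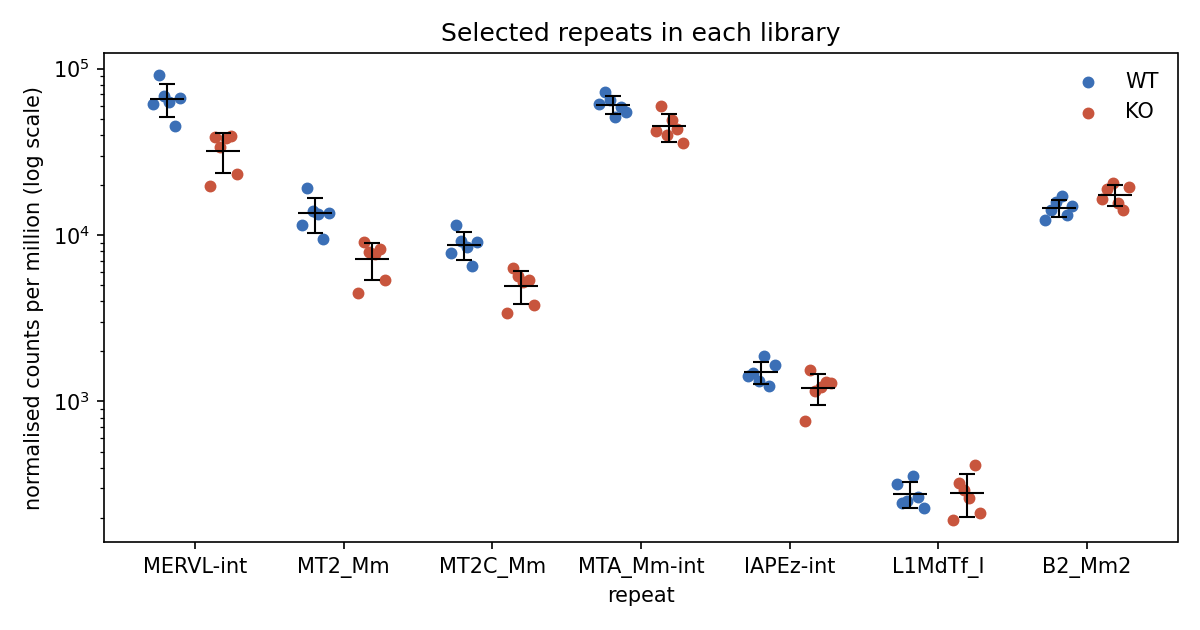
Normalised CPM (log scale) of 7 repeats in each library, WT in blue and KO in red, with 1 point per library and the mean ± SD of 6 libraries in black. MERVL-int, its terminal repeat MT2_Mm and the related terminal repeat MT2C_Mm show no overlap between the groups. L1MdTf_I, chosen after its values were seen, stands at 278 in WT and 283 in KO.

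The MT elements, nonautonomous LTR retrotransposons of the ERVL-MaLR family that are abundant in oocyte RNA, gave no single call in the list of 10. EdgeR found 8 of the 10 lower at an unadjusted p under 0.05, and the same 8 of 10 when adjusted over the list alone. DESeq2 called 6 lower and limma-voom with quality weights 1. The median log2 fold change of the list was -0.42, and camera placed it below the other repeats (adjusted p = 2.01e-07). With an estimated correlation the call was lost (adjusted p = 0.0910), and under total-count scaling edgeR called 2 members higher. The members with the smallest p were ORR1A0, with a log2 fold change of -0.59 (standard error 0.14, edgeR adjusted p = 0.0510), and ORR1A2, with -0.33 (standard error 0.09, edgeR adjusted p = 0.0755). The most abundant member, MTA_Mm-int, was chosen after its values were seen. It stood at 60785 ± 7640 normalised CPM in WT and 45017 ± 8541 in KO (SD, n = 6, edgeR adjusted p = 0.0901). As a share of all counts, the list stood at 12.5% ± 0.883 in WT and 11.7% ± 1.18 in KO (n = 6, exact permutation p = 0.210).

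The fall of MERVL-int was also seen against MTA_Mm-int within each library, a ratio that needs no scaling. The log2 ratio of MERVL-int to MTA_Mm-int was 0.10 ± 0.27 in WT and -0.51 ± 0.35 in KO (SD, n = 6, exact permutation p = 0.0108, adjusted p = 0.0216). All 6 KO libraries lay below the WT median, and 3 of them below every WT library. Outside the list, ORR1A0-int and ORR1A3-int of the same family, chosen after their values were seen, had log2 fold changes of -0.54 and -0.52 (edgeR adjusted p = 0.0359 and 0.0487).

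Intracisternal A particles, or IAP, are young endogenous retroviruses of the ERVK family. Of 25 IAP rows, 2 fell and 23 did not pass the test over all repeats; adjusted over the list alone, 7 were lower. IAPLTR2a fell from 99.5 ± 22.6 to 53.1 ± 10.5 normalised CPM (SD, n = 6), a log2 fold change of -0.91 (standard error 0.16, edgeR adjusted p = 0.0159). IAPLTR2_Mm had a log2 fold change of -0.51 (standard error 0.11, edgeR adjusted p = 0.0362), a call that was lost under total-count scaling (-0.20) and without each of 10 single libraries (all but KO replicates 2 and 6), with edgeR adjusted p up to 0.0929. The list had a median log2 fold change of -0.34 and lay below the other repeats by camera (adjusted p = 1.02e-10), but not with an estimated correlation (adjusted p = 0.0910). As a share of all counts, the list stood at 0.408% ± 0.0553 in WT and 0.407% ± 0.0437 in KO (n = 6, exact permutation p = 0.989).

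LINE-1 elements of mouse, the rows named L1Md, did not all change in the same direction between the genotypes (14 positive and 11 negative log2 fold changes). Of 25 rows, 2 fell and 23 did not pass; adjusted over the list alone, 4 were lower. L1MdA_II fell from 8287 ± 1906 to 4441 ± 1198 normalised CPM (SD, n = 6), a log2 fold change of -0.90 (standard error 0.19, edgeR adjusted p = 0.0293). L1MdGf_II fell from 4259 ± 585 to 2765 ± 376, a log2 fold change of -0.62 (standard error 0.11, edgeR adjusted p = 0.0157). The list's median log2 fold change was 0.01 while its mean was -0.12 and camera gave a lower direction (adjusted p = 0.00745), so these differ in sign. The camera result was lost with an estimated correlation (adjusted p = 0.494), and without WT replicate 4 (0.193), KO replicate 1 (0.202) or KO replicate 6 (0.258), and its direction turned under total-count scaling (adjusted p = 0.925). The call of L1MdA_II was lost without each of 7 single libraries (WT replicates 1, 3, 4 and 6, KO replicates 1, 3 and 6), with edgeR adjusted p up to 0.0769.

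The level of L1MdA_II followed that of MERVL-int from library to library. Over the 6 WT libraries, its share of counts had a Pearson r of 0.993 with that of MERVL-int (exact permutation p = 0.00139, adjusted p = 0.0347) and a Spearman rho of 1.0 (exact permutation p = 0.00278, adjusted p = 0.0694). Over the 6 KO libraries, r was 0.981 (exact permutation p = 0.00278, adjusted p = 0.0347) and rho 0.943 (exact permutation p = 0.0167, adjusted p = 0.208). Adjustment was over 50 relations, 25 L1Md rows in each group. Without the 2 libraries farthest from the median MERVL-int share, r was 0.978 in WT and 0.858 in KO. For L1MdGf_II, r was 0.07 in WT (rho = 0.03, exact permutation p = 1.0 for rho) and 0.517 in KO (rho = 0.771, exact permutation p = 0.103 for rho). L1MdMus_II and L1MdF_III, chosen after their values were seen, had r of 0.972 and 0.934 in WT and 0.966 and 0.959 in KO, and held 2 of the 4 relations with an adjusted p under 0.05 (both in KO, exact permutation, adjusted p = 0.0347 each). Without the 2 farthest WT libraries their r in WT was 0.559 and 0.393. Of the 25 L1Md repeats, 21 had r below 0 in WT, yet several of these had a high r in KO. Among them were L1MdA_VI, L1MdA_I and L1MdF_II, chosen after their values were seen (r = 0.927, 0.908 and 0.905, with exact permutation adjusted p = 0.139, 0.191 and 0.191). Without the 2 farthest KO libraries, KO replicates 1 and 6, their r in KO was 0.963, 0.077 and 0.230.

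**Figure D4:**
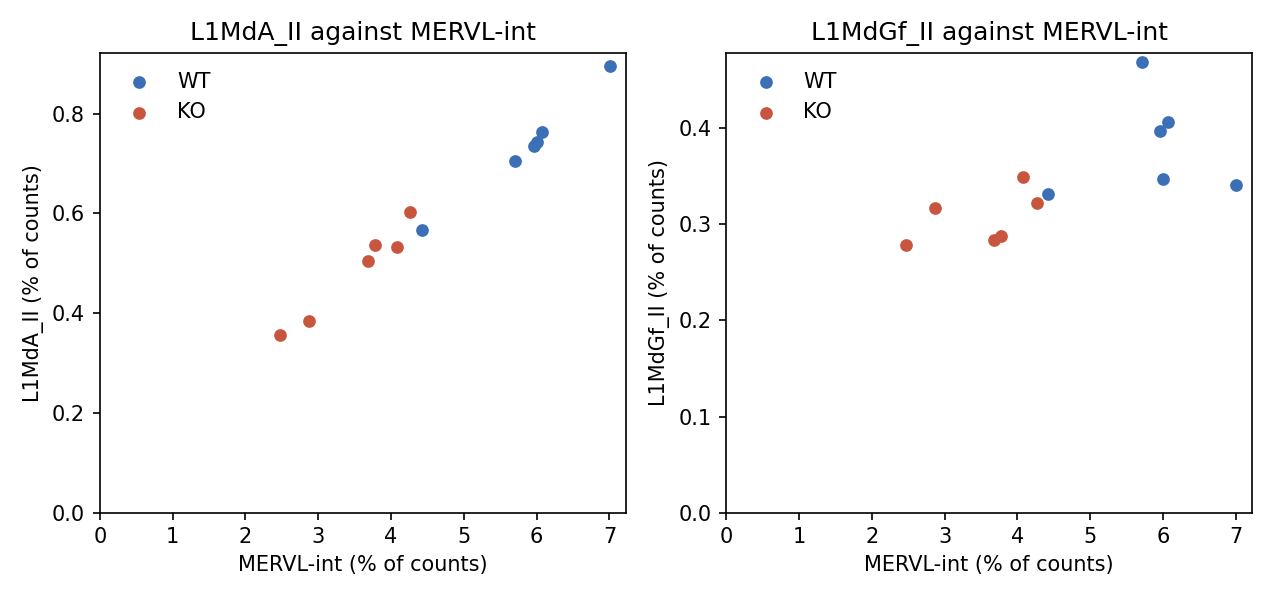
Share of all counts (%) of L1MdA_II (left) and L1MdGf_II (right) against the share of MERVL-int (%), with 1 point per library, WT in blue and KO in red. L1MdA_II lies along a line in both groups (r = 0.993 in WT and 0.981 in KO), and L1MdGf_II does not in WT (r = 0.07).

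None of the 6 SINE rows of the list passed edgeR's test over all repeats or when adjusted over the list alone. At an unadjusted p under 0.05, 3 were higher, and neither DESeq2 nor limma-voom with quality weights called any. The members with the smallest p belong to the B2 group of rodent SINEs. B2_Mm2 stood at 14571 ± 1765 normalised CPM in WT and 17510 ± 2464 in KO (SD, n = 6), a log2 fold change of 0.27 (standard error 0.10, edgeR adjusted p = 0.258), and was higher than the WT median in 5 of 6 KO libraries. B2_Mm1t had a log2 fold change of 0.31 (standard error 0.13, edgeR adjusted p = 0.298). Camera gave an adjusted p of 0.0643 for the list, and 0.413 with an estimated correlation. Under total-count scaling both B2 rows passed, with log2 fold changes of 0.58 and 0.61 (edgeR adjusted p = 0.00909 and 0.0118).

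Beyond these lists, the repeats with the largest falls among those with a mean of at least 10 normalised CPM included 1 simple repeat with an uncommon motif, _GAGATAA_n. It fell from 22.2 ± 5.58 to 3.21 ± 1.71 (SD, n = 6), a log2 fold change of -2.81 (standard error 0.37, edgeR adjusted p = 0.00669). ERVB4_2-LTR_MM, a terminal repeat of the ERVK family, fell by 1.12 on the log2 scale, MER89 of the ERV1 family by 1.08 and UCON12, a conserved repeat of unknown class, by 1.08 (edgeR adjusted p = 0.0177, 0.0302 and 0.0149). The simple repeats _GAGCAA_n and _GGCAG_n fell by 1.04 and 0.97 (edgeR adjusted p = 0.0212 and 0.0271). The call of ERVB4_2-LTR_MM was lost without KO replicate 6 (adjusted p = 0.0654). Those of MER89, _GAGCAA_n and _GGCAG_n were lost without 8, 4 and 7 of the single libraries, with edgeR adjusted p up to 0.0769, 0.0660 and 0.0767.

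Of the 5 repeats that rose, 3 had a mean of at least 10 normalised CPM. RLTR20A, a terminal repeat of the ERVK family, rose from a mean of 17.3 to 41.0 normalised CPM (n = 6), a log2 fold change of 1.24 (standard error 0.29, edgeR adjusted p = 0.0495). The DNA transposons MER113 and Charlie12_Rodent, both of the hAT-Charlie family, had log2 fold changes of 0.61 and 0.43 (edgeR adjusted p = 0.0413 and 0.0212). The remaining 2, chosen after their values were seen, were _GACAGA_n with a log2 fold change of 1.45 and LTR82B with 1.24, from means of 4.04 and 3.10 normalised CPM in WT (edgeR adjusted p = 0.0179 and 0.0402). The calls of RLTR20A, MER113 and Charlie12_Rodent were lost without 11, 9 and 5 of the 12 single libraries, with edgeR adjusted p up to 0.118, 0.103 and 0.0627.

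Many single calls also depended on the filter and on 2 libraries. Without WT replicate 2 and KO replicate 5, the calls of MT2_Mm, MT2C_Mm, MT2B, IAPLTR2_Mm, L1MdA_II, ERVB4_2-LTR_MM, MER89, _GAGCAA_n, _GGCAG_n, Charlie12_Rodent and RLTR20A were lost (edgeR adjusted p = 0.0561 to 0.126). With no filter, the same repeats except ERVB4_2-LTR_MM were lost, and MER113 as well (edgeR adjusted p = 0.0585 to 0.145). Against a fold of 1.5, only _GAGATAA_n passed. RLTR20A and MER113 were also lost with RLE factors (edgeR adjusted p = 0.0562 and 0.0564) and without the 20 most abundant repeats (0.0566 and 0.0544), RLTR20A with limma-voom (0.141) and with library size as a covariate (0.0664), and IAPLTR2_Mm with ERVL and ERVL-MaLR left out of the totals (0.0690).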

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

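Predictions were written only after the results had been seen for library scaling, slower development and both LINE-1 explanations. The same holds for the SINE share among counts outside the LTR class. Total-count scaling itself was a setting chosen beforehand. The other predictions were written before their results were seen. Of these, removal of WT replicate 2 and KO replicate 5 and totals without ERVL and ERVL-MaLR used settings chosen after seeing the data.

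Satellite repeats made up 3.56% of the counts in KO replicate 5, against 1.99% to 2.42% in the other KO libraries, a value set apart by a test for a single distant sample. After thinning of every library to 7952526 counts, 4449 repeat names were detected in WT replicate 2 against 5143 to 5462 in the other WT libraries, set apart by the same test. Chance sets apart about 1 in 20 groups, or 4.9 of the 98 groups tested, and 2 were found.

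The first pattern weighed was the fall of MERVL-int and its list in KO. Among 100 splits of the 12 libraries into 6 and 6, the real one gave the most calls (47, highest other 2; 1 of 100 splits reached it) and the strongest MERVL list result (-log10 p of 11.4, highest other 9.63; 1 of 100), which argues against a random grouping. The log2 fold change of MERVL-int was -0.99 (standard error 0.19) without WT replicate 2 and KO replicate 5, -0.73 (standard error 0.13) under total-count scaling and -1.13 (standard error 0.17) with library size as a covariate. The edgeR adjusted p was 0.0396, 0.00753 and 0.00727. These values argue against WT replicate 2 as its source, and against scaling or depth as measured from repeat counts. KO replicate 5 had the highest MERVL-int share of the KO libraries (4.27%), so it could not be the source of a fall. KO replicates 1 and 6, with the lowest shares (2.48% and 2.87%), were not removed together. All scaling and the covariate came from repeat counts, so scaling or depth measured outside them was not tested. Slower development of KO embryos would leave more stored MTA_Mm-int RNA, but its log2 ratio to counts outside the LTR class differed by -0.38 (standard error 0.11, exact permutation p = 0.0108). As a share of all counts, MTA_Mm-int stood at 5.43% in WT and 4.97% in KO (exact permutation p = 0.149), so its fall depended on the total used. Neither value tells delay from genotype, since the oocyte's genotype could itself set the stored level. For the MT and IAP lists a random grouping was not excluded, as 6 of 100 splits did as well in each (real 6.92 and 10.4, highest other 9.05 and 12.5).

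The second pattern was the fall of L1MdA_II alongside MERVL-int. If reads of MERVL loci were counted under this LINE-1 name, its KO share would follow the line fitted on WT libraries. The observed share was 1.10 times the predicted one (standard error 0.017), and the prediction counted only a share below the line against that source. The KO shares of MERVL-int (2.48% to 4.27%) all lay below the lowest WT share (4.42%), so the line was extended beyond its range. The standard error leaves out the error of that line. The ratio therefore neither supports nor excludes that source. A lower level across LINE-1 was not found, since the 22 L1Md repeats with r under 0.8 against MERVL-int in WT had a median log2 fold change of 0.0117. The standard error of that median, 0.020, was taken over repeats and not over libraries. The L1Md repeats were correlated (0.738 as estimated by camera), so it understates the spread between libraries. For the LINE-1 list as a whole, 44 of 100 splits did as well as the real one (2.22, highest other 18.0), so a random grouping was not excluded.

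The third pattern was the rise of other repeats under total-count scaling and of the SINE share. With the ERVL and ERVL-MaLR families left out of the totals, the median log2 fold change of repeats outside them was 0.0918 (standard error 0.058), against 0.319 with them, so fewer counts of these families could account for most of that rise. The SINE share among counts outside the LTR class still differed by 4.33 percentage points (exact permutation p = 0.00649), which argues against loss of LTR counts as its only source. A change in SINE level and a change in gene transcripts that carry SINEs were not told apart.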

How the results depend on the processing

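Only the settings said to be chosen after seeing the data were added once results had been seen. Main values were 47 calls, 5 higher and 42 lower. Calls came to 390 (357 higher) under total-count scaling, 169 (42 higher, 127 lower) with DESeq2, 71 (8 higher) with limma-voom, 18 (1 higher, 17 lower) with no filter, 112 (21 higher, 91 lower) at 10 or more CPM in 6 libraries, 72 (67 lower) with library size as a covariate and 1 (0 higher, 1 lower) against a fold of 1.5. Higher calls were 3 with RLE factors and 2 without the 20 most abundant repeats. Chosen after seeing the data, removal of WT replicate 2 and KO replicate 5 gave 23 (19 lower), tests of transposons only 126 (31 higher, 95 lower), totals without ERVL and ERVL-MaLR 16 higher, and TMM factors from transposons 64 calls. Leaving out 1 library gave 19 to 93 calls, 1 to 9 higher and 18 to 84 lower. The cause of these moves was not tested. The number of repeats tested alone does not set the count, since 3457 were tested without KO replicate 2 (93 calls) and 3460 without WT replicate 6 (19 calls).

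MERVL-int was lower in every setting that kept it (it is among the 20 most abundant repeats), at -1.13 to -0.93 without single libraries; against a fold of 1.5 its log2 fold change of -1.04 did not pass (edgeR adjusted p = 0.750). The MERVL list passed in all 20 settings in which lists were tested, with camera adjusted p from 1.68e-12 to 1.12e-10 without single libraries. These values rest on the preset correlation of 0.01. With the estimated correlation of 0.543, the camera adjusted p was 0.0300. Among other splits of the 12 libraries the camera -log10 p of this list reached 9.63, so such small p-values overstate the evidence. With an estimated correlation the MT, IAP and LINE-1 lists were lost (camera adjusted p = 0.0910, 0.0910 and 0.494). The LINE-1 list turned direction under total-count scaling (0.925), was lost at 10 or more CPM (0.107), and ran from 0.000161 to 0.258 without single libraries. The SINE list passed under total-count scaling (0.00109), upper quartile factors (0.0407), no filter (0.00917) and without WT replicate 2 and KO replicate 5 (0.00813), and ran from 0.00949 to 0.371 without single libraries. Differences without single libraries were -8.99 to -7.46 percentage points for the LTR share, 4.03 to 5.28 for the SINE share and -2.62 to -2.11 for the MERVL-int share. With structural RNA left out of the totals, chosen after seeing the data, the LTR and SINE shares differed by -8.90 and 5.20. The log2 ratio of MERVL-int to MTA_Mm-int differed by -0.71 to -0.50. Values of the named repeats kept direction and side of the threshold in 492 comparisons, passed newly in 16, were lost in 128 and turned in 0.

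With the replicate number as a replicate block, edgeR gave 48 calls, 1 higher and 47 lower, and the SINE list passed (camera adjusted p = 0.0418). Named calls not made with the block were RLTR20A, MER113, Charlie12_Rodent, IAPLTR2_Mm and _GGCAG_n (edgeR adjusted p = 0.119, 0.0728, 0.0674, 0.0549 and 0.0504), and ORR1A0 was newly called (0.0433). Same-numbered libraries had r from -0.07 to 0.15, with 1 of 6 pairs over 0.1 and 1 WT library closest to its own number, so the numbers were not taken as pairs. Normalization on gene counts and the Kdm4a level were not run, since the tables held repeats only. Depth limits rare repeats: 49.3% of simulated log2 changes of 1 were recovered, and 93.8% at 10 or more CPM.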

Other observations

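The repeats named here, other than _GAGATAA_n, _GAGCAA_n and UCON12, were chosen after their values were seen, and so were the tests on them. The RLTR6 group of the ERV1 family fell in KO in its internal and terminal parts. RLTR6-int and RLTR6_Mm had log2 fold changes of -0.63 and -0.62, RLTR6B_Mm of -0.88 and RLTR6C_Mm of -0.86 (edgeR adjusted p = 0.0212, 0.0212, 0.0217 and 0.0149). RLTR1B-int, MLTR18_MM and RLTR9D also fell, by 0.55, 0.91 and 0.56 on the log2 scale (each with an edgeR adjusted p of 0.0149). MamRTE1, a LINE repeat, fell by 0.81 (edgeR adjusted p = 0.0212), and its share followed that of MERVL-int (r = 0.939 in WT and 0.913 in KO), as did those of UCON12 (0.833 and 0.808) and _TCTTGC_n (0.838 and 0.811).

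The simple repeats with the 2 largest falls, _GAGATAA_n and _CTCTTAT_n, are the same 7-base motif on the 2 strands, with log2 fold changes of -2.81 and -2.51 (edgeR adjusted p = 0.00669 and 0.0149). The next largest falls had no called partner with the same motif: _AGAGCGCA_n, _AATTAAT_n and _CTTGTC_n had log2 fold changes of -2.48, -2.09 and -1.93 (edgeR adjusted p = 0.0149, 0.0359 and 0.0149). _GAGCAA_n and _TCTTGC_n share a motif, with log2 fold changes of -1.04 and -0.95, and were 2 of the 6 names tested for it. _TCTTGC_n stood at 139.5 normalised CPM in WT and 72.5 in KO, and _CTCTTAT_n at 14.3 ± 4.07 normalised CPM in WT and 2.55 ± 1.44 in KO (SD, n = 6).

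Of 38 families of the annotation, 9 passed camera, 6 higher and 3 lower, and 0 passed with an estimated correlation. hAT-Charlie DNA transposons lay higher (adjusted p = 0.000833; adjusted p = 0.287 with an estimated correlation). So did the L1 family of 149 repeats (adjusted p = 0.0211; 0.647 with an estimated correlation), opposite to the L1Md list, the SINE families B4, B2 and MIR (adjusted p = 0.0211, 0.0265 and 0.0265; 0.436, 0.417 and 0.475 with an estimated correlation) and L2 (adjusted p = 0.0357; 0.386 with an estimated correlation). ERVK, ERV1 and ERVL-MaLR lay lower (adjusted p = 0.000124, 0.000285 and 0.0265; adjusted p = 0.429, 0.349 and 0.475 with an estimated correlation).

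The repeat 7SLRNA made up 0.0553% of the counts in WT replicate 2, against 0.302% to 0.675% in the other WT libraries. GSAT_MM made up 0.0783% in KO replicate 1, against 0.365% to 0.795% in the other KO libraries. Neither value was set apart by the test for a single distant sample.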
